A study of Mus musculus with 8 samples.

How the data were processed

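Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on 2 kinds of mouse oligodendrocyte, the myelin-forming cell of the brain. Differentiated cells were grown from neural stem cells of an FvB and C57BL6 hybrid background that carried introduced PPARb with an HA tag, at passage 7. Isolated cells were taken from C57BL6 mouse brains with beads against O4, a surface marker of the oligodendrocyte lineage, at passage 0. Antibodies were against Qki-5, PPARb, HA and RNA polymerase II (Pol II) in the differentiated cells, and against Qki-5 and PPARb in the isolated cells. Each of the 8 groups, input included, had 1 library, so no difference could be set against a spread between replicates. The 6 antibody libraries had a peak list each, and the 2 input libraries entered only through the values the peak caller derived from them.

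Per the submitters' processing notes the tools included bcl2fastq 2.19.1.403, Trim Galore 0.4.4, Bowtie 1.2.2, SAMtools 1.8 and HOMER 4.10.1, with the genome build mm10. The notes used here give no role or order for these tools. Per the file headers, peaks were called by the authors with HOMER findPeaks in factor style at a false discovery rate of 0.001, and had to reach 4-fold and a Poisson p of 0.0001 over input, and 4-fold over the surrounding 10000 bp. Per the file headers, duplicate reads had been removed, as the names of the tag directories show, and all differentiated-cell lists were called against 1 input library and both isolated-cell lists against another. The tag directories of the differentiated-cell Qki-5 library and of the isolated-cell input carry the word merge, and what was merged is not given in the sources used here. All peaks were 200 bp wide, with their centres at least 400 bp apart by the caller's setting.

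The normalized tag count of a peak is a signal, scaled by the authors to 10000000 tags per library, per the file headers. The fold over input and the fold over the local background are ratios made by the authors' peak caller, per the file headers. The total tags of a peak are raw counts in 4 of the lists and, in the PPARb and Pol II lists of differentiated cells, a signal scaled to the depth of the input, per the file headers. The text calls the normalized tag count the peak height. It is the authors' value for each peak, and was used to describe, rank and filter peaks within a list. Intervals of single heights are 95% exact Poisson intervals of the tag number, and intervals of shares are 95% exact Clopper-Pearson intervals. Both cover counting error only.

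Library depth ranged from 12624236 to 24880851 tags. A peak of median height held between 14 and 22 tags, so the 95% interval of a median peak in the differentiated-cell Qki-5 library ran from 6.76 to 17.1 tags per 10000000. In the isolated-cell PPARb library only 0.117% of tags lay in peaks, against 4.62% in the HA library, so a missing peak there says that none was detectable at this depth.

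Peaks on chromosomes 1 to 19, X and Y entered the comparisons. Lists were compared by an overlap of at least 1 bp. The second list was shifted 1000 times along its chromosomes by random distances, and the fold is the observed number of overlapping peaks over the mean of the shifts. The smallest p that 1000 shifts can give is 0.001. Chromosome lengths were taken as the last annotated or called position. Gene positions came from a RefSeq table of the assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on these chromosomes. That table holds no strand and no exons. The planned distance to the transcription start site was therefore replaced by the distance to the nearer end of a protein-coding gene, called the gene boundary below, and a peak within 1000 bp of it is a boundary peak. A boundary can be the start or the end of the gene, and introns, exons and UTRs were not told apart. Motif searches, which need the genome sequence, were not run.

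Heights of peaks with and without a partner peak were compared by two-sided permutation tests with 100000 resamples, whose smallest p is 1e-05. Pol II and PPARb occupancy of Qki-5 peaks were related by a two-sided Fisher's exact test. For 18 gene lists, fixed with the other choices before the data were examined, boundary peaks were compared with all other protein-coding genes by two-sided Fisher's exact tests in 6 libraries and in the genes with both Qki-5 and PPARb boundary peaks in either cell kind. The 144 p-values were adjusted together by the Benjamini-Hochberg method, with a threshold of 0.05. All 417 list entries matched a gene. The lists of fatty acid oxidation and of known PPAR targets share 8 genes. Peaks and genes are not replicates, so each p describes these libraries and not the cells at large.

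Genes were named by a rule fixed in advance. It takes 13 genes in any case, then per list up to 4 members with boundary peaks in both the Qki-5 and PPARb lists of differentiated cells, ordered by the smaller of their 2 percentile ranks, and up to 4 members with a boundary peak in either list of isolated cells, ordered by the larger rank. It adds the 10 genes with the highest smaller rank over Qki-5, PPARb and HA in differentiated cells, the 10 over Qki-5 and PPARb in isolated cells, and the 5 tallest peaks of each library. Genes named outside this rule are said to be so. Some genes that the rule takes are not reported here.

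Alternatives were a threshold of 8-fold over input, the 2000 tallest peaks, peaks over 1000 bp from a boundary, centres within 100 bp (a minimum share of each peak selects the same pairs, since all peaks have 1 width), shifts that kept the share of boundary peaks, Pol II peaks widened by 1000 bp, windows of 500 and 5000 bp, fold over input in place of height, and genes with a Pol II boundary peak as background. Peaks anywhere in a gene's span, and Qki-5 peaks away from both Pol II and boundaries, were added after seeing the data. The overlap step was tested on simulated data: of 5000 overlaps planted among 25000 simulated peaks against the 30175 differentiated-cell Qki-5 peaks, 4959 were recovered above chance. Without planted overlaps the observed number was 0.892 of the shift mean. Planted peaks lay within the overlap distance and the rest at random, so this checks the counting and not whether the shifts suit real peak lists. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.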

Results

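Binding of Qki-5, the nuclear isoform of the RNA-binding protein Quaking, and of PPARb, a lipid-sensing nuclear receptor encoded by Ppard, was mapped by ChIP-seq in mouse oligodendrocytes. Differentiated cells, grown from neural stem cells with introduced HA-tagged PPARb, gave 30179 Qki-5, 26406 PPARb, 30042 HA and 13270 Pol II peaks. Isolated cells, taken directly from mouse brain, gave 8380 Qki-5 and 1393 PPARb peaks. Sequencing depth was 18078176, 22471011, 12624236 and 24880851 tags for the 4 differentiated-cell libraries in that order, and 21832339 and 18389111 tags for the isolated-cell Qki-5 and PPARb libraries. Tags in peaks made up 3.66%, 2.78%, 4.62% and 1.39% of the differentiated-cell libraries, but 0.849% and 0.117% of the isolated-cell libraries. Each antibody and cell kind had 1 library, so no value below has a replicate error, and intervals cover counting error only. Peak heights are the authors' tag counts scaled to 10000000 tags per library, and positions are on mm10.

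In differentiated cells Qki-5 and PPARb occupied largely shared sites. Of 30175 Qki-5 peaks, 19653 overlapped a PPARb peak, a share of 65.1% (95% exact interval 64.6 to 65.7). They made up 74.4% (73.9 to 74.96) of the PPARb list. Random shifts of the PPARb list gave a mean of 128.3 overlaps and at most 173, so the observed number was 153-fold the mean (permutation p = 0.001, the smallest that the shifts can give). With the share of boundary peaks kept in the shifted list, the mean rose to 1075 and the fold was 18.3. These shifts put boundary peaks at random ends of any protein-coding gene, occupied or not, and scattered the rest. The fold therefore still includes any preference of both factors for the same genes.

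With the full lists, the tagged receptor gave like figures. HA peaks overlapped 73.5% (73.0 to 74.0) of PPARb peaks and 66.7% (66.1 to 67.2) of Qki-5 peaks, 150-fold and 137-fold the shift means (permutation p = 0.001 for each). Whether PPARb peaks met Qki-5 or HA more often depended on the peaks taken. In the full lists 3445 overlapped Qki-5 alone and 3199 HA alone (exact McNemar p = 0.00265). The direction turned among the 2000 tallest peaks of each list, with 40.2% of PPARb peaks at Qki-5 and 45.1% at HA (exact McNemar p = 0.00111), and at 8-fold over input, with 67.6% and 71.97% (exact McNemar p = 4.35e-26). At 8-fold the partner lists differed in length, with 20021 Qki-5 and 23430 HA peaks. These settings were chosen for this comparison after the data were seen. Qki-5 and HA overlapped least among the tallest, at 30.4% (28.3 to 32.4). Sites in all 3 lists numbered 16208 by PPARb peak, 61.4% of the list, and 13.5% of PPARb peaks overlapped neither of the others. Across those 16208 sites, which are not independent replicates, PPARb heights ranked with Qki-5 heights at a Spearman rho of 0.69 and with HA heights at 0.66. All 4 differentiated-cell lists were called against the same input library, so part of the overlap may come from that shared control. It could not be simulated from peak lists.

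**Figure D1:**
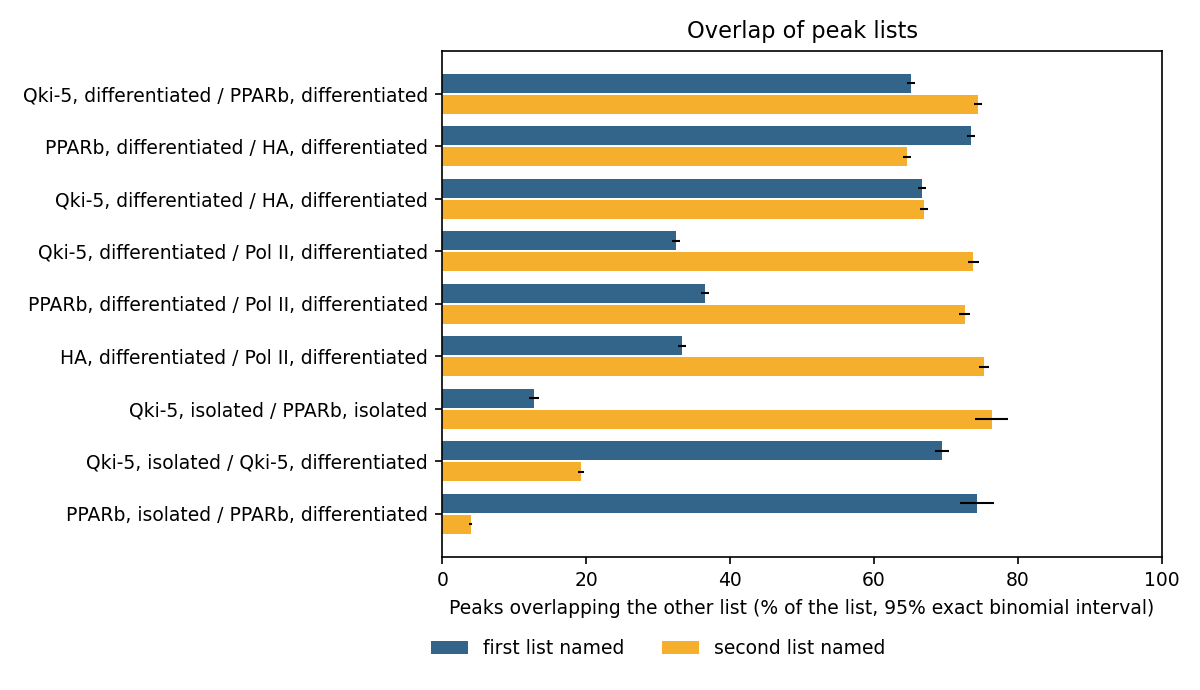
Overlap of peak lists, with the percentage of each list that overlaps the other by at least 1 bp on the horizontal axis and the pair of lists on the vertical axis. Blue bars give the first list named and yellow bars the second, 1 library each, and black lines are 95% exact binomial intervals. The Qki-5 and PPARb lists of differentiated cells overlap by 65.1% and 74.4%.

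Pol II marks transcribed genes, and its peaks coincided with all 3 lists. Of the 13267 Pol II peaks, 73.8% (73.1 to 74.6) overlapped Qki-5, 72.7% (71.9 to 73.4) PPARb and 75.3% (74.6 to 76.1) HA. These overlaps were 151-fold, 169-fold and 154-fold the shift means (permutation p = 0.001 for each). Qki-5 peaks with Pol II carried PPARb in 86.8% (86.2 to 87.5) of 9795 cases, and those without Pol II in 54.7% (54.0 to 55.4) of 20380. The odds ratio was 5.47 (5.12 to 5.84), with a two-sided Fisher's exact p too small to be written as a number. With Pol II peaks widened by 1000 bp on each side it was 3.50. Away from both Pol II and gene boundaries, 8348 of 15690 Qki-5 peaks still overlapped PPARb, 125-fold the shift mean.

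Shared sites were taller. The median Qki-5 height was 12.7 at sites with PPARb (quartiles 9.4 and 16.6) and 8.3 without (6.64 and 11.1), a difference of 4.4 (two-sided permutation p = 1e-05, the smallest possible). PPARb height was 10.7 with Qki-5 and 7.12 without, a difference of 3.58 (permutation p = 1e-05). By fold over input, the same PPARb comparison gave 10.6 and 9.71 (permutation p = 1e-05). PPARb was found at 89.1% of Qki-5 peaks in the top quintile of height and at 30.9% in the bottom quintile. In isolated cells, Qki-5 peaks with PPARb were taller by 3.7 (12.4 against 8.7, permutation p = 1e-05). The PPARb peaks of isolated cells did not pass the test, with medians of 8.16 and 7.61 that lie 1 tag apart (permutation p = 0.629). Over 1000 bp from a boundary the same comparison passed, with a difference of 0.54 (permutation p = 0.00483).

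Single lipid genes showed the range of occupancy. At Angptl4 (chromosome 17, 33774900 to 33781575), a lipase inhibitor and known PPAR target, a site inside the gene at 33779345 to 33779545 held the PPARb peak of rank 3 in differentiated cells, at 39.2 (31.4 to 48.3). The HA peak there reached 99 (82.4 to 118), the Qki-5 peak 15.5 (10.3 to 22.4), and the PPARb peak of isolated cells 19 (13.3 to 26.5). No Pol II peak and no Qki-5 peak of isolated cells was called at the site. Cpt1a (chromosome 19, 3322326 to 3385735) encodes an enzyme needed for the entry of fatty acids into mitochondria. A site inside the gene at 3325394 to 3325594 had an HA height of 122.8 (104.2 to 143.7), the tallest HA peak on the assembled chromosomes. PPARb reached 22.7 (16.9 to 29.8) and Qki-5 10.5 (6.33 to 16.4) there. Plin2, a lipid droplet coat protein on chromosome 4, had boundary peaks of 7.19 for Qki-5, 9.35 for PPARb and 12.7 for HA, and none in isolated cells. Pdk4, a kinase that restrains pyruvate oxidation and a known PPAR target on chromosome 6, had no peak in any list within 5000 bp of its span.

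**Figure D2:**
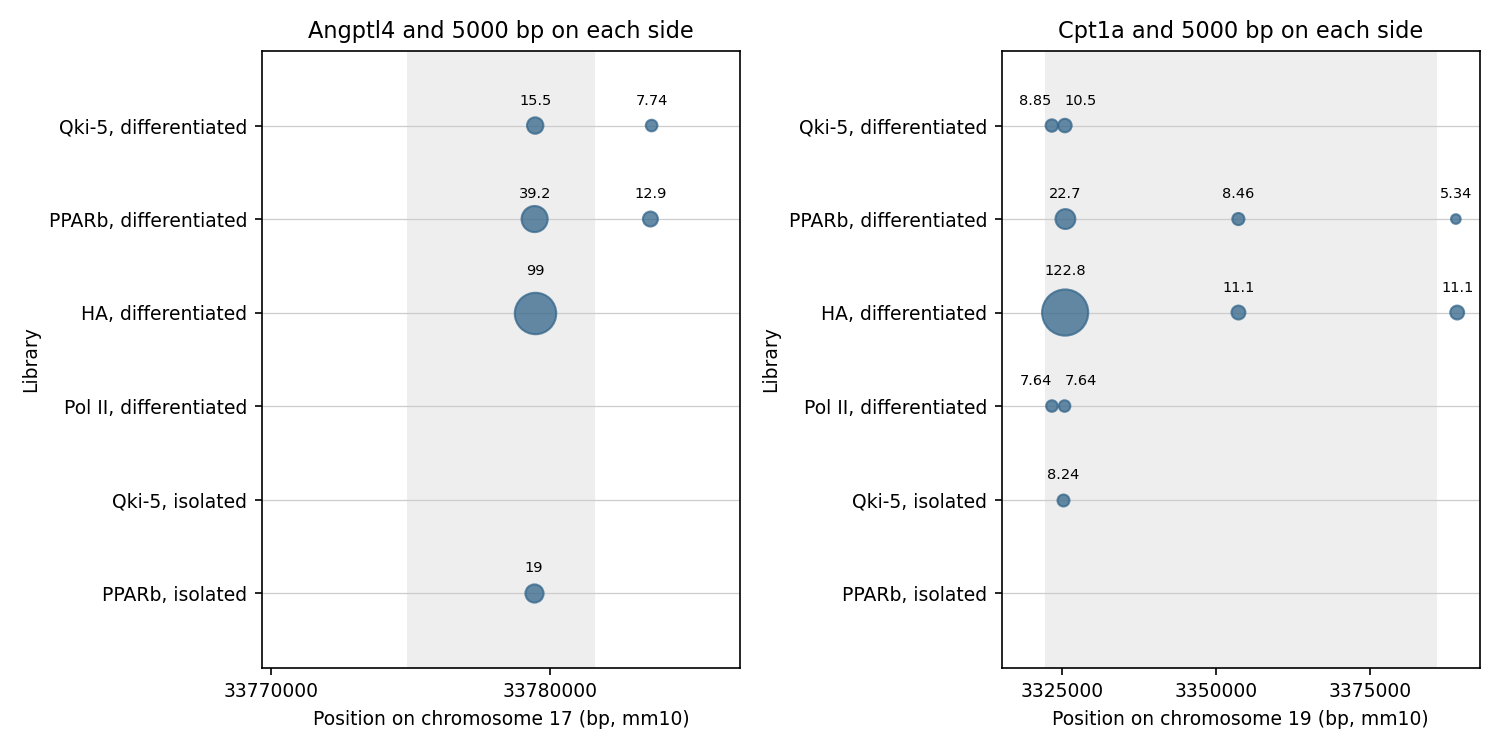
Peaks within 5000 bp of Angptl4 (left) and Cpt1a (right), with the mm10 position in bp on the horizontal axis and the 6 libraries on the vertical axis. Each dot is a peak, its area and the number above it give the height in tags per 10000000, and grey marks the gene's span. The HA peaks of 99 and 122.8 are the tallest of each panel.

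The genes of the factors themselves were also occupied. Qk, which encodes Quaking, had boundary peaks of 11.6 for PPARb, 23.8 for HA and 17.3 for Pol II, and 11 for Qki-5 in isolated cells, while its Qki-5 peak in differentiated cells lay inside the gene at 6.64. Ppard had boundary peaks of 10.5 for Qki-5 and 18.2 for HA, and of 7.79 for Qki-5 and 6.53 for PPARb in isolated cells. Tags from introduced PPARb sequence were not separated from those of Ppard itself. Among the RXR partners of PPARb, Rxra had 4 Qki-5 and 4 PPARb peaks in differentiated cells and none in isolated cells, Rxrb had boundary peaks in all 6 lists, and Rxrg had a single weak PPARb peak of 5.34 and an HA peak of 9.51. Mbp, a major myelin protein, had differentiated-cell peaks inside the gene at 82538176 to 82538376 on chromosome 18. Their heights were 14.4 for Qki-5, 17.8 for PPARb and 23 for HA. Near the lineage regulators Sox10 and Olig2 the peaks lay outside the gene spans, with HA heights of 12.7 and 27.7.

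Genes of energy and lipid metabolism were among those most often occupied by both factors. Overall 40.0% of the 21887 genes had boundary peaks of both Qki-5 and PPARb in differentiated cells. Both were at 22 of 24 citric acid cycle genes, with an odds ratio of 16.5 (4.06 to 145, Fisher's exact adjusted p = 3.83e-06). They were at 21 of 27 fatty acid oxidation genes (5.25, exact adjusted p = 0.000515) and at 19 of 23 cholesterol synthesis genes (7.13, exact adjusted p = 0.000289). Pol II alone had a like excess at fatty acid oxidation genes, 37.77 percentage points over other genes (exact adjusted p = 0.000459) against 37.79 for both factors. The excess is therefore not particular to Qki-5 and PPARb. Fatty acid synthesis, elongation and desaturation had 20 of 33 (2.31, exact adjusted p = 0.0457), a call lost with peaks anywhere in the gene span (exact adjusted p = 0.147). Named members include Acaa2, an enzyme of beta-oxidation, with heights of 19.4 for Qki-5, 19.1 for PPARb and 103.8 for HA. Etfdh and Acadm stood at 20 and 19.1 for PPARb. Scd4, a desaturase, had 21 for Qki-5 and 27.6 for PPARb, and Fasn, the fatty acid synthase, 21 and 14.7, with Fads1 and Acaca also bound. Mvk of the mevalonate pathway had 24.9 and 22.3, ahead of Hmgcs1, Sqle and Mvd. Sdha, Sdhb and Suclg1 were among the leading citric acid cycle genes, at 16.5, 15.6 and 13.8 for PPARb.

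The list of known PPAR targets did not stand out, with 7 of 24 genes (odds ratio 0.616, exact adjusted p = 0.432), among them Acaa2, Hadha and Acadvl. Its strongest site by PPARb height, at Angptl4, lies over 1000 bp from the gene's ends. Sphingolipid genes had 13 of 23 (exact adjusted p = 0.224), with Kdsr, Far1, Sptlc2 and Agps named by the rule. Nuclear receptors had 17 of 28 (exact adjusted p = 0.0707), among them Nr1d1, Ppara, Rxrb and Nr1h2. Splicing factors passed with 23 of 35 (2.88, exact adjusted p = 0.00921), led by Sf1, U2af2, Hnrnpa1 and Hnrnpa2b1, and ribosomal proteins with 30 of 36 (7.51, exact adjusted p = 3.12e-06), led by Rpl23, Rps19, Rpl27 and Rpl11. The list named core histones, which also holds linker histones such as H1f4, had 10 of 17 (exact adjusted p = 0.224), with H4c3, H4c4, H1f4 and H4c14 named by the rule.

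Myelin, endothelial and other-tissue genes were occupied less often within 1000 bp of their boundaries. Myelin genes had both factors at 3 of 30, Tmem88b, Qdpr and Car2 (0.166, exact adjusted p = 0.00239), endothelial and mural markers at 0 of 13 (exact adjusted p = 0.00876), and genes of other tissues at 1 of 30, Apoa1 (0.0515, exact adjusted p = 5.71e-05). The myelin deficit depended on the window: it was -30.1 percentage points against other genes at 1000 bp and -10.2 at 5000 bp (exact adjusted p = 0.406). Over whole gene spans, chosen after the data were seen, neither myelin genes (-11.2 points, exact adjusted p = 0.397) nor endothelial markers (-28.1 points, exact adjusted p = 0.103) passed. The lineage transcription factor list had 4 of 13 (Zfp24, Yy1, Tcf7l2 and Zeb2), precursor and stem cell markers 4 of 18 (among them Fabp7, Ptprz1 and Sox6), astrocyte markers 4 of 13 (Atp1b2, Acsbg1, Aldoc and Slc1a2), neuron markers 2 of 15 (Map2 and Snap25) and microglia markers 2 of 15 (among them Spi1), and none of these 5 passed the exact test. Over the 18 lists, 6 were over-represented and 3 under-represented among genes with both factors. Pol II alone gave 8 and 3. For genes with both factors among the 2000 tallest peaks of their libraries, ribosomal proteins alone passed (exact adjusted p = 0.023). Taken singly, the 2000 tallest PPARb peaks kept fatty acid oxidation over-represented (exact adjusted p = 0.00147), as did those of HA (exact adjusted p = 1.92e-08), while those of Qki-5 did not (exact adjusted p = 1). Genes with a Pol II boundary peak were too uniformly bound to serve as a background for over-representation, since 88.95% of them carried both factors. Fatty acid oxidation had 19 of 20 there, and 20 of 20 would have given an unadjusted exact p of 0.158.

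**Figure D3:**
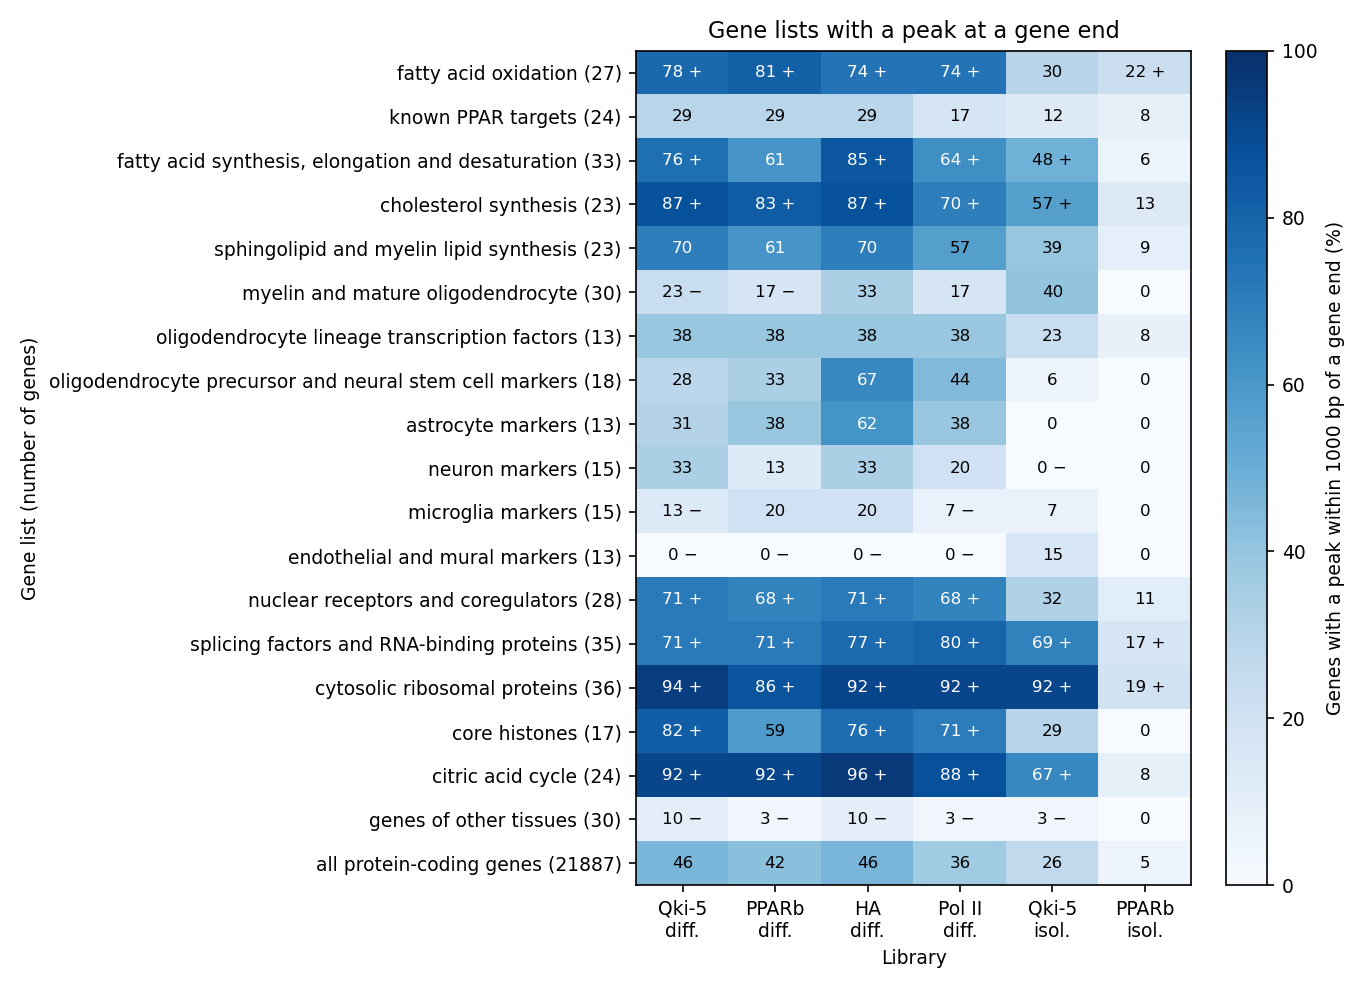
Percentage of each gene list with a peak within 1000 bp of a gene end (colour and number), with the 6 libraries on the horizontal axis and the 18 lists and all protein-coding genes on the vertical axis. Plus and minus mark lists over- or under-represented at an adjusted Fisher's exact p under 0.05. Citric acid cycle genes stand at 91.7% in the Qki-5 and the PPARb lists of differentiated cells, and endothelial and mural markers at 0.

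The isolated cells, which carried no introduced PPARb, showed how many of their own sites were also bound in differentiated cells. Of 8375 Qki-5 peaks, 5819 overlapped a differentiated-cell Qki-5 peak, 69.5% (68.5 to 70.5) and 141-fold the shift mean (permutation p = 0.001). Of 1391 PPARb peaks, 1034 overlapped a differentiated-cell PPARb peak, 74.3% (71.95 to 76.6) and 172-fold (permutation p = 0.001). In the other direction, these overlaps covered only 19.3% (18.8 to 19.7) of differentiated-cell Qki-5 peaks and 3.92% (3.685 to 4.157) of PPARb peaks. Most differentiated-cell sites thus had no isolated-cell peak, and binding there below detection was not told apart from no binding. These 2 comparisons join lists called against different inputs. Within isolated cells, 1062 PPARb peaks overlapped Qki-5, 76.35% (74.02 to 78.6) of the PPARb list but 12.7% (11.98 to 13.4) of the larger Qki-5 list, 566-fold the shift mean (permutation p = 0.001). With the share of boundary peaks kept in the shifts, which leaves in any preference for the same genes, the 3 folds were 8.89, 9.39 and 15.1.

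In isolated cells, Qki-5 boundary peaks were over-represented at ribosomal protein genes (33 of 36, odds ratio 30.8, exact adjusted p = 3.3e-14), splicing factors (24 of 35), the citric acid cycle (16 of 24), cholesterol synthesis (13 of 23) and fatty acid synthesis (16 of 33). Named members are Rpl27 at 30.7, Rpl32 at 23.4, Rps19 at 21.1 and Rpl4 at 20.2, Srsf2 and Ptbp1 at 20.6 and 20.2, Sdhb at 17.4, Mvk at 22, Hmgcs1 at 18.8, and Tecr and Hacd2 at 12.8 and 12.4. With Pol II-bound genes of differentiated cells as background, ribosomal proteins alone of these lists passed (32 of 33, exact adjusted p = 0.000123). Among the 2000 tallest peaks, fatty acid synthesis (exact adjusted p = 0.973) and the citric acid cycle (exact adjusted p = 0.874) did not pass. Neuron markers (0 of 15, exact adjusted p = 0.0384) and genes of other tissues (1 of 30, exact adjusted p = 0.00612) were under-represented in the Qki-5 list of isolated cells. PPARb boundary peaks of isolated cells were over-represented at fatty acid oxidation genes, 6 of 27 (odds ratio 5.44, 1.79 to 13.97, exact adjusted p = 0.0064), among them Acadl at 13.1, Etfa at 10.9, and Hadha and Hadhb at 8.16, which share 1 boundary region. In the same cells Qki-5 was at 8 of the 27 (exact adjusted p = 0.781) and both factors at 4 (exact adjusted p = 0.0707). Ribosomal proteins (7 of 36) and splicing factors (6 of 35) also passed, and the other 15 lists did not. The splicing call was not robust to the family of tests: adjusted with the 2000 tallest peaks of the other libraries, the same PPARb list gave an exact adjusted p of 0.0699. With the smaller Pol II-bound background none of the 3 passed the exact test, and the excess over other genes went from 17.2 to 13 percentage points for fatty acid oxidation, from 12.2 to 9.43 for splicing factors and from 14.5 to 6.18 for ribosomal proteins. No PPARb boundary peak was found at the 30 myelin genes at this depth.

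Some myelin genes had a Qki-5 boundary peak in isolated cells and no overlapping one in differentiated cells. Of the 12 myelin genes with a Qki-5 boundary peak in isolated cells, 8 had peaks without a differentiated-cell counterpart alone, against 784 of 5769 other genes (odds ratio 12.7, 3.395 to 57.8, Fisher's exact p adjusted over the 18 lists = 0.000642). This comparison, and the genes it names, were chosen after the data were seen. The 8 are Mag, Cnp, Mobp, Gal3st1, Hapln2, Tspan2, Gpr37 and Pllp, with heights between 5.95 and 9.16, and they belong to the myelin sheath or to mature oligodendrocytes. That library had a median height of 9.16 and a calling threshold of 13 tags, with a height of 0.458 per tag. All 8 thus lay at or below the median, and the lowest lay near the threshold. Ndrg1, Car2, Tmem88b and Qdpr were bound in both. Endothelial markers also had isolated-cell Qki-5 boundary peaks, at Cldn5 (5.95) and Flt1 (5.5), both near the calling threshold. Both were without a counterpart (2 of 2 genes, exact adjusted p = 0.169).

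Location relative to genes differed between the cell kinds. In differentiated cells 32.8% (32.3 to 33.4) of Qki-5, 33.5% (32.9 to 34.1) of PPARb and 34.2% (33.7 to 34.8) of HA peaks lay within 1000 bp of a gene boundary, and 56.2% (55.4 to 57.1) of Pol II peaks. In isolated cells the share was 60.5% (59.4 to 61.5) for Qki-5 and 65.9% (63.3 to 68.3) for PPARb. Shifted lists gave about 3.1%. Taller peaks were more often at boundaries, with 55.7% in the top quintile of differentiated-cell Qki-5 heights and 13.04% in the bottom quintile. Among the 2000 tallest peaks the share was 61.8% for Qki-5 and 35.2% for PPARb in differentiated cells, and 83.7% for Qki-5 in isolated cells.

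**Figure D4:**
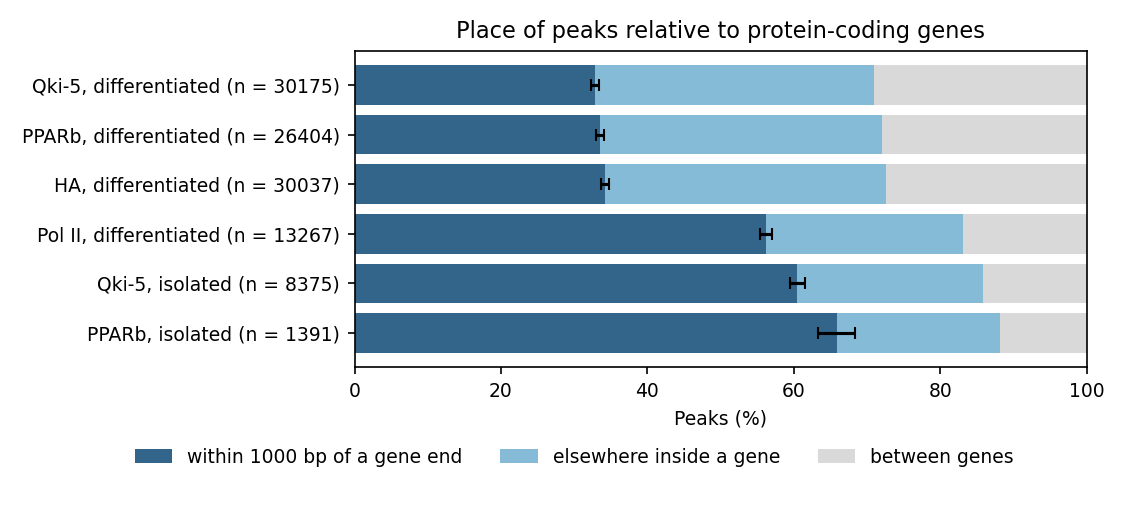
Place of peaks relative to protein-coding genes, with the percentage of peaks on the horizontal axis and the 6 libraries on the vertical axis. Dark blue is within 1000 bp of a gene end, light blue elsewhere inside a gene and grey between genes, and black lines are 95% exact binomial intervals of the dark blue share. It is 32.8% to 34.2% for the 3 factor lists of differentiated cells and 60.5% and 65.9% in isolated cells.

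The genes ranked highest over Qki-5, PPARb and HA in differentiated cells were Hjurp, a centromere histone chaperone (52.5, 40.1 and 57.8), Hspd1 and Hspe1, which share a boundary region and encode mitochondrial chaperonins (32.1, 28.9 and 55.4), Mrpl45, Ythdf2, Ccdc191, Qtrt2, Uspl1, Psmd3 and Ap1g1. In isolated cells they included Hjurp (29.8 for Qki-5 and 17.9 for PPARb), Rpl27, 2810408A11Rik, Neurl4, Myo9a, Senp8, Rap2a, Ubald2 and Ccdc103. By fold over input Hjurp did not lead, with 12.47 for Qki-5, 9.5 for PPARb and 12.19 for HA in differentiated cells. The list medians there were 11.55, 10.14 and 14.28. In isolated cells Hjurp had 6.61 for Qki-5 and 4.38 for PPARb, against medians of 6.71 and 5.98. The tallest PPARb peak of differentiated cells, at 19784553 to 19784753 on chromosome 8 and 31050 bp from 4930467E23Rik, reached 50.7 at 6.42-fold over input. It was followed by sites at Hjurp, Angptl4, Ldlrad3 and Txnip. After Cpt1a, the tallest HA peaks lay at Klf10 (121.2), Cldnd2 (114.1) and Acaa2 (103.8). On the assembled chromosomes the Qki-5 list was led by a site on chromosome Y (82.4, 4.74-fold over input), 2 sites in or near 4930467E23Rik (66.4 and 65.8) and Kmt2a (58.1, 220.5-fold over input). Kmt2a also held the tallest Qki-5 peak of isolated cells, at 42.1, ahead of Wwox, Rpl27, Hjurp and Mrpl47. The tallest Pol II peaks included those at Polr2a (102.9), Gadd45g, Atp1b2 and Tob1. In the isolated-cell PPARb list, sites near Foxf1 (32.1) and Pisd (21.8) came first and had no peak in any other list, ahead of Tmcc3, Galnt2 and Angptl4.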

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

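Peaks on sequences outside chromosomes 1 to 19, X and Y took no part in the comparisons, yet each library held some. They lie above input by construction, since the caller required 4-fold over input of every peak. The tallest of all in the Qki-5 and HA lists of differentiated cells lay on the same unplaced sequence, with heights of 159.9 and 159.2 but only 4.27-fold and 4.44-fold over input. The tallest such peaks in the other lists were 9.01-fold over input for PPARb and 5.34-fold for Pol II in differentiated cells, and 6.15-fold for Qki-5 and 6.64-fold for PPARb in isolated cells. No biological explanation was tested for them.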

How the results depend on the processing

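Peaks anywhere in a gene's span, Qki-5 peaks away from Pol II and boundaries, and the alternatives for the share of PPARb peaks with Qki-5 against that with HA were chosen only after the results were seen. Each of the 9 overlaps stayed above all shifts under every alternative run, with folds from 8.893 (boundary preference kept) to 1321 (at least 8-fold over input). The share of PPARb peaks with Qki-5 minus that with HA turned from 0.932 percentage points to -4.385 at 8-fold over input and -4.9 among the 2000 tallest; the cause was not tested. With centres within 100 bp and over 1000 bp from a boundary it kept its direction, at 1.886 and 0.786. Height differences kept their direction, and that of isolated-cell PPARb passed the test over 1000 bp from a boundary, at 0.54; the cause was not tested. The planned searches for binding elements, with their alternatives, were not run. Only 0.849% and 0.117% of tags lay in peaks in the isolated-cell Qki-5 and PPARb libraries, so an absent peak there means that none was detectable.

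At 8-fold over input, 20024 Qki-5, 16626 PPARb and 8127 Pol II peaks of differentiated cells were left, and 2969 Qki-5 and 374 PPARb peaks of isolated cells, by construction of the threshold. Boundary shares moved with the window, also by construction. At 500 bp they were 28.22% (Qki-5), 29.08% (PPARb), 28.68% (HA) and 50.08% (Pol II) in differentiated cells, and 55.56% (Qki-5) and 61.39% (PPARb) in isolated cells. At 5000 bp they were 43.94%, 44.44%, 45.87%, 65.92%, 71.37% and 76.28% in that order. Among the 2000 tallest peaks they were 61.8%, 35.2%, 42.6%, 82.55% and, for isolated-cell Qki-5, 83.7%; the cause was not tested.

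Of the 18 gene lists, those over-represented fell from 8 (Qki-5), 6 (PPARb), 8 (HA), 6 (both factors), 3 (isolated-cell PPARb) and 2 (both, isolated) to 0 with Pol II-bound genes as background, and from 5 to 1 for isolated-cell Qki-5. In differentiated cells this was fixed by construction, since 95.59% (Qki-5), 91% (PPARb), 96.28% (HA) and 88.95% (both) of the 7956 background genes were bound. Even a wholly bound list could give no unadjusted exact p below 0.402, 0.0694, 0.625 and 0.0448 in that order. In isolated cells the longer lists had no such ceiling, while the shortest could not pass even if wholly bound, such as myelin (5 genes, exact p = 0.0848) for Qki-5, and the endothelial list had no member. Among the 2000 tallest peaks 1 list was over-represented for Qki-5, 2 for PPARb, 1 for HA, 3 for Pol II, 1 for both factors, 3 for isolated-cell Qki-5 and 1 for both in isolated cells, with fewer bound genes by construction. Lists under-represented numbered 4 for Qki-5, and 2 at 5000 bp, 1 with the Pol II background, 0 among the tallest and 2 over gene spans. For PPARb they were 3, and 0, 0 and 1 with the Pol II background, among the tallest and over gene spans. They fell to 0 under the Pol II background and among the tallest peaks for HA, isolated-cell Qki-5 and both factors, and among the tallest for Pol II.

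Among genes with both factors, the calls lost over gene spans were fatty acid synthesis (15.49 points), myelin (-11.22) and endothelial markers (-28.14), and at 5000 bp myelin (-10.21). Some lists changed direction, given here as percentage points of bound genes, list minus other genes. With the Pol II background in differentiated cells, 88.95% to 96.28% of genes were bound, so a list had little room above other genes. The microglia list held 1 gene there and the myelin list 5. Any other cause was not tested. With the Pol II background Qki-5 had fatty acid oxidation at -0.5897, fatty acid synthesis and the citric acid cycle at -0.3511 each, cholesterol synthesis at -1.842, myelin at 4.415, microglia at 4.412, nuclear receptors at -0.8534 and splicing factors at -6.325. PPARb had nuclear receptors at -1.53, splicing factors at -1.721 and ribosomal proteins at -3.135. HA had fatty acid oxidation at -1.283, cholesterol synthesis at -2.535, nuclear receptors at -1.546, ribosomal proteins at -2.35 and histones at -12.97. Genes with both factors had fatty acid synthesis at -12.8, splicing factors at -6.833 and ribosomal proteins at -1.077. Isolated-cell Qki-5 had fatty acid synthesis at -2.24 and genes of other tissues at 40.63, the latter from 1 gene.

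Among the 2000 tallest peaks, Qki-5 had nuclear receptors at -7.045, and PPARb nuclear receptors at -0.4406 and the citric acid cycle at -4.016. HA had cholesterol synthesis at -4.459, ribosomal proteins at -1.68, histones at -4.458 and the citric acid cycle at -0.2883, and Pol II had fatty acid oxidation at -1.083. Genes with both factors had fatty acid oxidation at -2.347, splicing factors at -2.348 and the citric acid cycle at -2.346, and isolated-cell Qki-5 had fatty acid synthesis at -6.455. Of the other list results, 26 lost their call with the Pol II background, 37 among the tallest peaks, 5 at 5000 bp and 10 over gene spans, all in the same direction.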

Other observations

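The tests below on Pol II and gene boundaries, on equal numbers of peaks, on PPAR-related genes and on the PPARb antibody at those genes were chosen only after the results they bear on were seen, while those on rank correlations, other brain cell types and ribosomal protein genes were written beforehand. The bound for the Qki-5 comparison of boundary shares was also revised after its value was seen, since at first any Qki-5 difference counted against introduced PPARb. The overlap of the tallest peaks was set beside the rank correlations only after both were seen.

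Tagged PPARb stood high against Qki-5 at fatty acid oxidation genes. At the 26 sites common to the Qki-5, PPARb and HA lists that lie within 5000 bp of a fatty acid oxidation gene or a known PPAR target, the median site ranked at the 84.8th percentile of HA height and the 77.8th of PPARb height but at the 42.9th of Qki-5 height among the common sites. The median log2 ratio of HA to Qki-5 height was higher by 0.74 than at the other 16182 sites (bootstrap interval 0.28 to 1.60, permutation p = 1e-05), and 18 of the 26 lay above the others' median. By list the difference was 1.06 for fatty acid oxidation (0.24 to 2.12) and 0.67 for known PPAR targets, with an interval that reached 0 (-0.08 to 1.59). It was also 0.22 for nuclear receptors (0.12 to 0.26, permutation adjusted p = 0.0156). Below the other sites lay cholesterol synthesis (-0.38, permutation adjusted p = 0.00996), the histone list (-0.49, permutation adjusted p = 0.00996) and ribosomal proteins (-0.36, permutation adjusted p = 0.0009). Sites at ribosomal protein genes had a median 1.10 below the PPAR-related sites (a difference of -1.1, permutation p = 1e-05). The median ribosomal site ranked at the 78.0th percentile of Qki-5 height and the 51.9th of HA height. A high ratio is thus not shared by that class of busy promoter, which has high Qki-5, and busy promoters in general are not decided. The ratio peaked at Cpt1a, followed by Pdgfra and Acadl, genes chosen after their values were seen. A candidate explanation is preferential binding of PPARb at genes of fatty acid oxidation. Whether the introduced receptor is needed for it was not tested. In isolated cells, without that receptor, PPARb boundary peaks were also over-represented at these genes (17.2 points over other genes, exact adjusted p = 0.0064). With Pol II-bound genes as background they did not pass (13 points, exact adjusted p = 0.471). Ribosomal protein and splicing factor genes passed in the same list, so the excess was not particular to fatty acid oxidation. Qki-5 boundary peaks did not pass at these genes, but no test compared PPARb with Qki-5 directly. A property of the HA antibody or library alone is argued against by the PPARb antibody in differentiated cells. Its log2 ratio to Qki-5 was also higher at the 26 sites, by 0.51 (bootstrap interval 0.08 to 0.59, permutation p = 1e-05). Both ratios share the Qki-5 library, and no cells without the tag were analysed here.

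The like overlap of the full Qki-5, PPARb and HA lists was weighed against 2 technical explanations. Called Pol II peaks and boundaries of protein-coding genes do not hold all of it. Away from both, 8348 of 15690 Qki-5 peaks overlapped PPARb, 125.4-fold the shift mean. The shifts place peaks without regard to open chromatin, so this fold cannot exclude Pol II sites too weak to be called or other promoters. The rank-correlation test written beforehand went with a common set of sites that every antibody pulls down alike. PPARb heights followed HA no more closely than Qki-5, with a difference in Spearman rho of -0.031 (bootstrap interval -0.041 to -0.021). The median HA peak held 17 tags and the median Qki-5 peak 20, and the difference was not corrected for this unequal counting error. The rho was 0.59 with HA and 0.67 with Qki-5 at boundaries, and 0.68 and 0.70 away from them. The overlap of the tallest peaks points the other way. The 2000 tallest PPARb peaks met HA (45.1%) more often than Qki-5 (40.2%). After both were seen, the question was therefore called undecided. Open chromatin and joint binding may both contribute, and no library with an unrelated antibody was analysed here to separate them.

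Qki-5 peaks of isolated cells with no differentiated-cell Qki-5 peak, called isolated-only here, numbered 2556, 30.5% of the list. Fewer, 1706 or 20.4%, had no peak in any differentiated-cell list. Of the 2556, 31.3% lay at gene boundaries against 73.3% of the shared ones. Other brain cells carried along with the O4-selected cells might add such peaks. The neuron, microglia, astrocyte and endothelial lists together had 2 of 3 genes with isolated-only boundary peaks, an odds ratio of 12.6 (0.656 to 745, Fisher's exact p = 0.0511), too few genes to decide. Over whole gene spans, chosen after seeing the data, it was 6 of 8 genes (14.4, 2.57 to 146), and all 6 were endothelial and mural markers. Myelin genes showed the same over whole spans, 14 of 21 (9.67, 3.64 to 28.4), as did precursor and stem cell markers, 5 of 6 (24.0, 2.68 to 1136). Lineage transcription factors did so too, 5 of 7 (12, 1.96 to 126). Endothelial cells and a difference in oligodendrocyte stage therefore both remain possible.

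Boundary shares of isolated cells stayed higher at equal numbers of peaks. The 1391 tallest PPARb peaks of differentiated cells had 33.1% (30.6 to 35.6) at boundaries, against 65.9% in isolated cells. The 8375 tallest Qki-5 peaks had 53.5% (52.4 to 54.6), against 60.5%. The Qki-5 difference depends on the number taken, with 61.8% and 83.7% among the 2000 tallest of each, and it does not decide whether introduced PPARb lies behind the PPARb difference. Strain and culture also differ with the cell kind.

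In a comparison chosen after the data were seen, only 4 of 1391 PPARb peaks of isolated cells lay on chromosome X, 0.288%, against 1.48% of Qki-5 peaks in the same cells (odds ratio 0.192, Fisher's exact p = 5.62e-05). The median peak held 14 tags in that PPARb list and 20 in that Qki-5 list, against a calling threshold of 13 tags in both. Whether peaks lost at the threshold add to the contrast was not tested.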
